A study of Mus musculus with 6 samples.

How the data were processed

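The series holds 6 Affymetrix arrays of total RNA from mouse BCR-ABL1 transformed pre-B cells, 3 transduced with the empty vector pMIG and 3 with pMIG carrying IKZF1, grouped by the transduction stated in the labels. Replicate numbers were taken from the sample titles. The values were normalized by robust multi-array average (RMA), per the submitters' processing notes; its version, the software and the annotation release are not given in the sources used here. The deposited values are probe set intensities on a linear scale: they run from 11.1 to 23523, with array medians between 100.2 and 107. RMA is usually given as log2, so the scale was read from the values. Background correction, quantile normalization and probe summarization belong to RMA as a method, and the deposited table gives no parameters for them. Quantile normalization equalises the distributions of arrays and would reduce a shift common to most genes. The signal of dim probe sets still holds background, so that fold changes of dim genes may be understated.

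From these values log2(intensity + 1) was computed, with a pseudocount of 1, and fold changes are on this scale. The design fixed for the tests had foreseen either log2 or linear values. The table holds 35421 probe sets, of which 21789 pair with 1 gene symbol in the platform's gene table, 1621 with several and 12011 are unnamed here. Symbols were updated through the gene number for 21698 probe sets of that table and through an accession for 3, and were kept as given for 88; the update changed 2 symbols. Only probe sets with 1 symbol were tested. For 1001 genes with over 1 such probe set, the brightest by its mean over the 6 arrays stood for the gene, which left 19936 genes. No filter on level was set. No genome was used here, so no positions are given. The number of arrays limits the precision; the intensities carry no read depth.

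Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a trend, 2-sided), with group as the only term, Benjamini-Hochberg adjustment over the 19936 genes and a threshold of an adjusted p under 0.05. Log2 differences are IKZF1 minus empty vector. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 29 lists together, of which 21 were study lists and 8 held markers of other cell types; a list needed 4 measured genes. Of 568 list entries 516 matched a tested gene, and the others were not analysed here. Some genes stand in over 1 list. Camera asks whether a list moved relative to the other genes. It was run again with the correlation estimated per list, and fry was run to test whether the genes of a list move one way on balance. Counts of members past the threshold are given over all genes and adjusted over the list alone.

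The groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Ikzf1 and its family, then the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap, leaving out unnamed gene models, small RNAs, receptor gene families and immunoglobulin or T cell receptor V segments, and up to 4 members of each list, those past the threshold first by size and then the smallest p. It named 131 genes, 46 of them past the threshold. A few further list members were named after their values were seen, as stated beside them or, in the closing section, because they belong to a hypothesis formed from the data.

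Replicate numbers are shared between the groups in the titles, with no statement of what they mark. The deviations of same-numbered arrays from their group means correlated across genes with r = 0.24, 0.60 and 0.66, and those of arrays with different numbers with r between -0.68 and 0.11. Every same-numbered pair lay above 0.1, the limit set for taking the numbers as pairs. Empty vector 1 with IKZF1 2, of different numbers, also lay above it (r = 0.11), so the limit did not separate pairs from other arrays. Deviations within a group cancel out by construction, so these correlations are not independent of each other. The pairing is thus not settled, and the fit with replicate number as a block is given beside a result where it changes the call or moves a count by over 1.5 times.

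The tests were run on simulated data for this comparison, with the 19936 genes at their measured levels and spread and 200 genes changed. Without a pair effect, the fit without a block recovered 58.8%, 92.4% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, and 4.05% of its calls were false. With a simulated pair effect it recovered 5.88%, 74.2% and 93.9%, and the fit with the block 2.94%, 84.8% and 97.0%. That pair effect was added on top of the measured spread, which already holds any real one. The genes then varied more than the measured genes, so these recoveries do not describe either fit on these arrays. The simulated calls were 117 without and 127 with the block, against 448 and 1438 in the data. In the list test, 3 of 3 lists shifted by 0.5 were called higher, and 0 of 29 were called where nothing was changed. The simulated genes varied independently of each other. This run therefore does not show how often the list test errs where genes of a list vary together.

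The alternatives were a trended or a robust prior, array weights, genes brighter than the median probe set, all probe sets, the mean of a gene's probe sets, another quantile normalization, arrays centred on their medians, cyclic loess, the replicate block, a minimum log2 difference of 1, a threshold of 0.01 and leaving out each array in turn. Chosen after seeing the data were log2 without a pseudocount, replicate number as a random block (duplicateCorrelation), removal of the loess trend of each array with level (span 0.4), and cyclic loess for the lists and named genes. Random gene lists for a comparison of medians were drawn 10000 times, matched on mean level. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.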

Results

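Gene expression was measured on Affymetrix arrays in mouse pre-B cells transformed by BCR-ABL1, the fusion kinase of Philadelphia chromosome-positive acute lymphoblastic leukaemia. The cells came from C57Bl6 mice aged 4 weeks and were transduced either with the empty retroviral vector pMIG, which carries a gene for green fluorescent protein (GFP), or with pMIG carrying IKZF1, the gene of the zinc finger transcription factor Ikaros. GFP-positive cells were sorted 3 days after transduction and their total RNA was hybridised. There were 3 arrays in each group, called empty vector 1 to 3 and IKZF1 1 to 3, and their number limits the precision of every value. The labels do not say whether the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

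The median intensity over all probe sets was 101, 102 and 100.2 on the empty vector arrays and 103, 107 and 102 on the IKZF1 arrays. The 100 brightest probe sets held 5.76% to 5.97% of the summed intensity of an array. The first principal component took 51.3% of the variance between arrays and did not separate the groups: empty vector 3 lay at -41.7 and IKZF1 2 at 24.5, at its opposite ends. The second took 33.9%, with empty vector 1 and 2 at -20.2 and -25.9, empty vector 3 at 2.34 and the IKZF1 arrays between 12.3 and 16.9. As a measure of background, 1190 olfactory and vomeronasal receptor genes had a median log2 level of 4.81, and 95% of them lay below 6.12 in the empty vector group and below 6.24 in the IKZF1 group.

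The comparison of IKZF1 with empty vector cells addressed which transcripts change when Ikaros is supplied to BCR-ABL1 transformed pre-B cells. Ikzf1 itself was 2.34-fold higher in the IKZF1 group, at a log2 level of 13.10 against 11.87, a difference of 1.23 ± 0.07 (SE, n = 3 arrays per group; limma, Benjamini-Hochberg adjusted p = 0.0021). The labels do not give the species or isoform of the insert, so it is open how far this probe set reads the transgene, endogenous Ikzf1 or both. The probe set, the only one of the gene, read 11.85, 11.78 and 11.98 on the empty vector arrays and 13.09, 13.14 and 13.06 on the IKZF1 arrays. A 2-sided exact permutation test of these 6 values gave p = 0.1, the smallest that 3 arrays against 3 allow. The other members of the Ikaros family did not pass the threshold: log2 differences were 0.09 for Ikzf2, 0.12 for Ikzf3, -0.01 for Ikzf4 and 0.17 for Ikzf5, with adjusted p of 0.48, 0.34, 0.99 and 0.23. A further probe set of Ikzf5 gave -0.06. In all 1 of 5 members was higher, also when adjusted over the list alone. The list holds the transduced gene itself, so its upward shift (camera adjusted p = 0.023) restates the transduction and says nothing of the other 4 members. The call was lost with an estimated correlation (adjusted p = 0.32), with the replicate block (adjusted p = 0.071), with the mean of probe sets (adjusted p = 0.067), and without empty vector 3 or IKZF1 2 (adjusted p = 0.083 and 0.064).

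Of 19936 genes tested, 448 passed the threshold of an adjusted p under 0.05, 223 of them higher and 225 lower in the IKZF1 group. A log2 difference of at least 1 was reached by 53 of the higher and 24 of the lower genes. The 3 IKZF1 arrays lay all above or all below the 3 empty vector arrays for each of the 448, and for 5285 genes in all, which is 26.5% of the genes tested where chance gives 10%. The 10% holds where all arrays are interchangeable, and does not allow for arrays of the same number varying together. With replicate number as a block, 1438 genes passed, 670 higher and 768 lower, and they included all 448. The count depended on single arrays: it was 28 without empty vector 1, 163 without empty vector 2, 947 without empty vector 3, 24 without IKZF1 1, 83 without IKZF1 2 and 85 without IKZF1 3.

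The largest rises were those of Ly6g, a surface protein used as a marker of granulocytes, and Ms4a1, which encodes the B cell antigen CD20. Ly6g was higher by 4.47 ± 0.21 (SE) on the log2 scale (adjusted p = 0.0014) and Ms4a1 by 4.17 ± 0.07 (adjusted p = 9.7e-06). In the empty vector group both lay within the background range, at log2 levels of 5.61 and 5.34, so the size of these rises rests on a background signal. The same holds for Cpe, which encodes carboxypeptidase E (log2 difference 2.73, level 6.03), and the collagenase gene Mmp13 (2.30, level 5.54). Transcripts of the receptor tyrosine kinase Ret rose by 2.90 ± 0.18 (adjusted p = 0.0024), those of Frmd5 by 2.62 ± 0.14 (adjusted p = 0.0014) and those of the sperm chromatin protein gene Prm1 by 2.54 ± 0.12 (adjusted p = 0.0014). Hepacam2 (3.47), Slfn1 (2.91), Hmces (2.27), the organic anion transporter gene Slco1b2 (2.13) and the vesicular glutamate transporter gene Slc17a8 (2.08) completed the 12 largest rises, with adjusted p between 0.0018 and 0.043. Of these 12, Hepacam2 and Slfn1 differed most between the empty vector arrays, with SDs of 1.14 and 0.80 on the log2 scale (n = 3).

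The 12 largest falls were led by Gpt2, Chac1 and Cth. The alanine aminotransferase gene Gpt2 fell by 2.58 ± 0.22 (SE) on the log2 scale (adjusted p = 0.0069), Chac1, whose product degrades glutathione, by 2.53 ± 0.13 (adjusted p = 0.0014), and Cth, which encodes cystathionine gamma-lyase, by 2.30 ± 0.28 (adjusted p = 0.019). The neutral amino acid transporter gene Slc1a4 had a log2 difference of -1.78 (adjusted p = 0.019) and the pseudokinase gene Trib3 one of -1.70 (adjusted p = 0.012). The receptor genes Tlr4 and Slamf9 both fell by 1.93, Trem1 by 1.63 and Itgal, the alpha chain of the integrin LFA-1, by 1.59, with adjusted p between 0.0042 and 0.029. Zfp229 (-1.50), Efcab11 (-1.44) and Gpm6b (-1.44) completed the group. Of the 45 named genes other than Ikzf1 past the threshold, 35 no longer passed without empty vector 1, 20 without empty vector 2, 34 without IKZF1 1, 30 without IKZF1 2 and 29 without IKZF1 3. Without empty vector 3, 0 were lost. Ly6g, Ms4a1, Ret, Frmd5, Prm1, Slc17a8, Chac1 and Slamf9 passed under each setting run, and Hmces did not pass with a robust prior (adjusted p = 0.062).

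**Figure D1:**
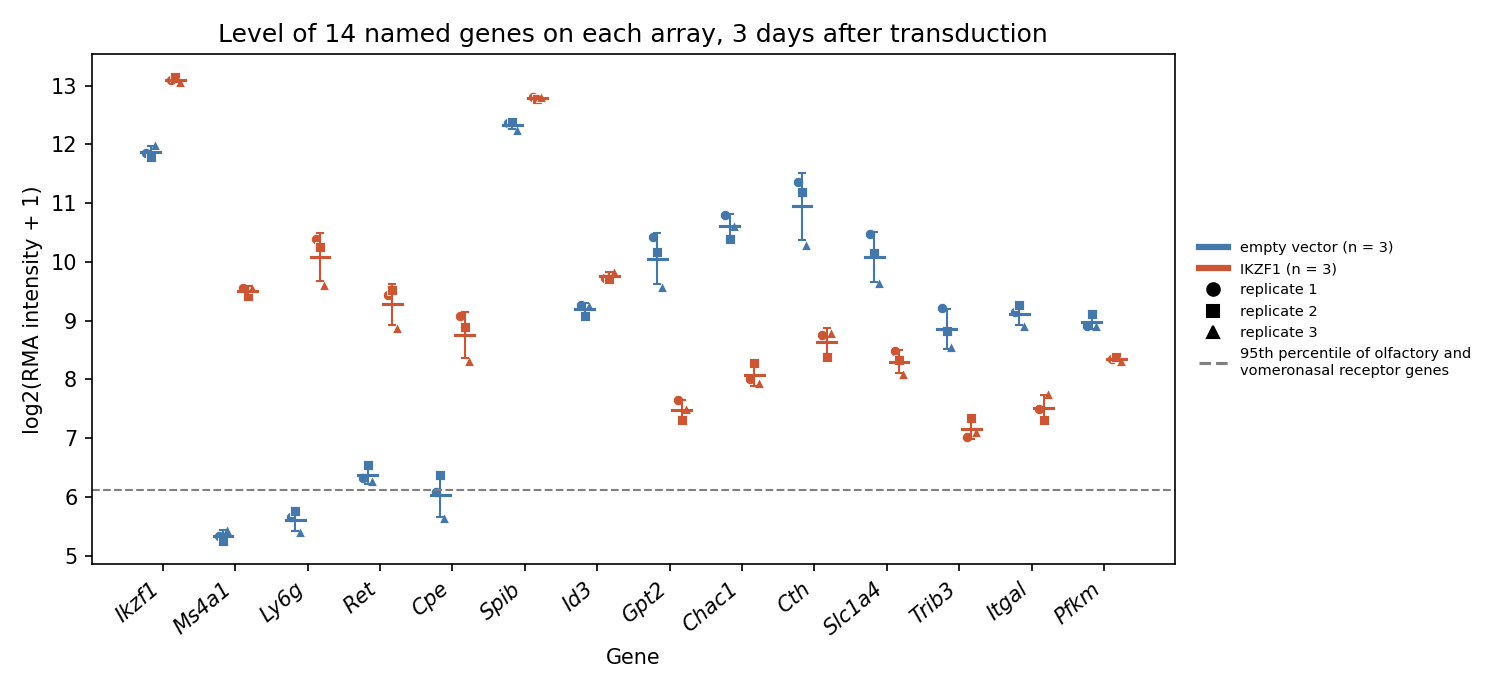
Log2(RMA intensity + 1) of 14 named genes on each array (vertical axis), with the empty vector group in blue and the IKZF1 group in orange, 1 symbol per replicate, a horizontal bar at the mean and an error bar of 1 SD over the 3 arrays. The groups do not overlap for any of these genes; Ms4a1, Ly6g and Cpe start at empty vector means below the dashed line, the level of 6.12 under which 95% of olfactory and vomeronasal receptor genes lie.

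Genes of maturing B cells were shifted upward as a list (camera adjusted p = 0.0027), a call lost with an estimated correlation (adjusted p = 0.34). The immunoglobulin light chain genes of that list had no probe set of 1 symbol and did not enter its test; probe sets with several symbols were counted apart from the lists. Of 27 measured members, 3 rose and 24 did not pass, and 21 had a log2 difference above 0 (median 0.33). The risers were Ms4a1, Id3, an inhibitor of E protein transcription factors (0.56, adjusted p = 0.024), and Spib, an Ets family transcription factor (0.46, adjusted p = 0.022). Cd40 had 0.47 (adjusted p = 0.052, and 0.019 with the replicate block). It passed as well with array weights, the random block, a robust prior, brighter genes, centring, cyclic loess and the level trend removed (adjusted p from 0.011 to 0.048). There were 7 members higher and 1 lower when adjusted over the list alone, and 8 and 1 with the block. Of 22 genes of the pre-B cell receptor and its proximal signalling, 1 rose, the Src family kinase gene Blk (0.62, adjusted p = 0.028), and 21 did not pass. Adjusted over the list alone 5 were higher and 1 lower. The list as such was not past the threshold (adjusted p = 0.41, and 0.047 with the level trend removed). Syk (0.32, adjusted p = 0.069) and Vpreb2, which encodes a surrogate light chain (-0.38, adjusted p = 0.11), passed with the replicate block (adjusted p = 0.047 and 0.030), where 2 members were higher and 1 lower. Syk passed as well with array weights, the random block, quantile normalization, cyclic loess and the level trend removed (adjusted p from 0.013 to 0.044). Vpreb2 also passed without empty vector 3 (adjusted p = 0.046). Of 24 early B-lineage and progenitor genes, 0 passed in limma, over all genes, adjusted over the list alone or with the block, and 4 had an unadjusted p under 0.05. That list was not shifted (adjusted p = 0.47). Tcf3 (0.20), Lef1 (0.31) and Pax5 (0.24) had adjusted p of 0.14, 0.18 and 0.23, with 0.028 for Lef1 without empty vector 3.

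Of 25 genes of glucose uptake and glycolysis, 2 fell and 23 did not pass. Both encode phosphofructokinase subunits, Pfkl (-0.65, adjusted p = 0.047) and Pfkm (-0.63, adjusted p = 0.017). Pfkl did not pass after quantile normalization (adjusted p = 0.058) or cyclic loess (adjusted p = 0.069), or with the level trend removed (adjusted p = 0.074). Tpi1 (-0.55, adjusted p = 0.067) and Pgk1 (-0.52, adjusted p = 0.068) passed with the replicate block (adjusted p = 0.022 and 0.024), where 5 members were lower and 1 higher, and without empty vector 3 (adjusted p = 0.012 and 0.023). A total of 7 were lower and 1 higher when adjusted over the list alone. The list was shifted downward (median -0.11, camera adjusted p = 0.0046), and this was lost with an estimated correlation (adjusted p = 0.32) and with fry (adjusted p = 0.066). Among 20 genes that restrain glucose supply or respond to glucocorticoids, Sesn2, an inhibitor of mTORC1 signalling, fell by 1.22 (adjusted p = 0.023), also when adjusted over the list alone, and 19 did not pass. Nr3c1, the glucocorticoid receptor gene, had -0.26 (adjusted p = 0.10). The list was not shifted (adjusted p = 0.84), its median of 0.09 and mean of -0.0056 differing in sign. Of 27 genes of oxidative phosphorylation, 0 passed in limma, also when adjusted over the list alone, 6 had an unadjusted p under 0.05, and 1 was higher with the block, Uqcrh (0.29, adjusted p = 0.11 and 0.047). That list was shifted downward (median -0.09, camera adjusted p = 0.0027), which was lost in 6 of 15 other settings: with an estimated correlation (adjusted p = 0.32), fry (0.066), brighter genes (0.076), quantile normalization (0.060), cyclic loess (0.20) and the level trend removed (0.14).

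The heat shock and unfolded protein response list gave the smallest p of the 29 lists (camera adjusted p = 1.2e-05, downward; adjusted p = 0.25 with an estimated correlation). Of its 18 members 5 fell and 13 did not pass, 14 had a log2 difference below 0 (median -0.24), and adjusted over the list alone 7 were lower and 1 higher. The 5 were Chac1, Trib3, the asparagine synthetase gene Asns (-1.22, adjusted p = 0.010) and the transcription factor genes Ddit3 (-0.85, adjusted p = 0.040) and Atf4 (-0.68, adjusted p = 0.0073), which belong to the branch of stress signalling that amino acid shortage also engages. Atf4 is named after its value was seen.

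MAPK feedback regulators were shifted downward (camera adjusted p = 2.3e-05; adjusted p = 0.21 with an estimated correlation). Of 12 members, 11 had a log2 difference below 0 (median -0.43), but 1 fell and 11 did not pass. Spred1, an inhibitor of Ras signalling, was the one that fell (-0.43, adjusted p = 0.047, and 0.056 with arrays centred on their medians). Spred2 (-0.43), Dusp7 (-0.42) and Etv5 (-0.66) had adjusted p of 0.059, 0.062 and 0.064 and passed with the replicate block (adjusted p = 0.034, 0.033 and 0.039), where 6 members were lower. The other probe set of Spred2 had -0.58 (adjusted p = 0.033 among all probe sets). Spred2 passed as well with array weights, the random block, the mean of its probe sets, quantile normalization, cyclic loess and the level trend removed (adjusted p from 0.017 to 0.046). Dusp7 did with array weights, the random block, a trended prior and centring (adjusted p from 0.010 to 0.044). Etv5 did with array weights and the random block (adjusted p = 0.0094 and 0.023). Without empty vector 3 Dusp7 and Etv5 had adjusted p of 0.021 and 0.0047. Adjusted over the list alone, 7 were lower and 1 higher. Of 13 genes of the NF-kB response, 4 rose and 9 did not pass: Nfkb2 (0.54), Cd83 (0.53), Nfkbia (0.50) and Relb (0.33), with adjusted p of 0.024, 0.019, 0.019 and 0.037. Cd83 and Relb did not pass once the trend with level was removed (adjusted p = 0.052 and 0.062), nor Relb with an intensity trend in the prior (adjusted p = 0.10) or with arrays centred on their medians (adjusted p = 0.067). Adjusted over the list alone 7 were higher, and the list shift (camera adjusted p = 0.0011) was lost with an estimated correlation (adjusted p = 0.32) and without empty vector 3 (adjusted p = 0.05003).

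Of 19 interferon response genes, 2 rose, Ifit3 (1.69, adjusted p = 0.024) and Ifit1 (0.78, adjusted p = 0.029), and 17 did not pass. Both started within the background range, at log2 levels of 5.50 and 5.47. The list median was 0.54, and 7 members were higher and 1 lower when adjusted over the list alone, and 8 and 1 with the replicate block. The list shift (camera adjusted p = 0.0027) was lost with an estimated correlation (adjusted p = 0.64), with fry (adjusted p = 0.20) and without empty vector 3 (adjusted p = 0.05003). In the BCL2 family and apoptosis list, 2 of 16 genes rose and 14 did not pass: Bcl2l1, which encodes the survival protein BCL-XL (0.64, adjusted p = 0.027), and Bcl2l11, which encodes the death-promoting protein BIM (0.55, adjusted p = 0.033, and 0.056 with arrays centred on their medians). When adjusted over the list alone, 5 were higher. The upward shift of this list (camera adjusted p = 0.0081) was lost with an estimated correlation (adjusted p = 0.32) and without empty vector 3 (adjusted p = 0.16). Of 17 STAT5 targets, Bcl2l1 rose, Spred1 fell and 15 did not pass, while 4 were higher and 1 lower when adjusted over the list alone. The list was not shifted (adjusted p = 0.42). Of 15 immediate early genes, 0 passed in limma and 6 had an unadjusted p under 0.05. Adjusted over the list alone 3 were higher and 1 lower. With the block 4 were higher and 2 lower, among them Atf3 (-1.18, adjusted p = 0.084, 0.048 with the block and 0.0040 without empty vector 3) and Nr4a1 (0.63, adjusted p = 0.15 and 0.040). That list was not shifted (adjusted p = 0.71).

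By its brightest probe set, no gene of the S and G2/M, Myc and ribosome biogenesis, G1 or brake lists passed the threshold in limma over all genes. Among 36 genes of S and G2/M phase, of which 0 passed also when adjusted over the list alone or with the replicate block and 1 had an unadjusted p under 0.05, Cdt1 (-0.25), Tk1 (-0.51) and Top2a (-0.25) had adjusted p of 0.19, 0.29 and 0.30. The list was shifted downward (median -0.07, camera adjusted p = 0.017), which was lost with an estimated correlation (adjusted p = 0.73), fry (0.70), brighter genes (0.23), quantile normalization (0.14), cyclic loess (0.28), the level trend removed (0.27) and without IKZF1 2 (0.30). Its direction turned without empty vector 3 (mean 0.052, adjusted p = 0.75). Of 27 Myc and ribosome biogenesis genes, 5 had an unadjusted p under 0.05, 1 was lower when adjusted over the list alone and 2 with the block, Npm1 (-0.59, adjusted p = 0.056 and 0.014) and Myc (-0.39, adjusted p = 0.20 and 0.041). Npm1 passed as well with array weights, the random block, a trended prior, brighter genes, cyclic loess and the level trend removed (adjusted p from 0.011 to 0.048). The ornithine decarboxylase gene Odc1 had -0.31 (adjusted p = 0.16) by its brightest probe set and -0.57 by its other (adjusted p = 0.029 among all probe sets). It passed with array weights and with the mean of its probe sets (adjusted p = 0.040 and 0.039). Without empty vector 3 Odc1 and Myc passed (adjusted p = 0.033 and 0.031). The downward shift of this list (camera adjusted p = 0.036) was lost with an estimated correlation (adjusted p = 0.69), fry (0.49), brighter genes (0.27), quantile normalization (0.16), cyclic loess (0.51), the level trend removed (0.55), and without empty vector 1, empty vector 3 or IKZF1 2 (adjusted p = 0.14, 0.43 and 0.15). Of the 8 D-type cyclin and G1 kinase genes, 0 passed over all genes, adjusted over the list alone, with the block or at an unadjusted p under 0.05 (list adjusted p = 0.39), Ccnd1 having -0.78 ± 0.37 (SE; adjusted p = 0.33, and 0.018 without empty vector 3). Of 19 cell cycle brakes, 0 passed over all genes or adjusted over the list alone and 7 had an unadjusted p under 0.05. With the replicate block 5 were higher, among them the kinase inhibitor gene Cdkn2c (0.80, adjusted p = 0.12 and 0.022) and Gadd45a (0.65, adjusted p = 0.13 and 0.023), which passed without empty vector 3 too (adjusted p = 0.020 and 0.047). The list missed the threshold (camera adjusted p = 0.059) and passed it in 10 of 15 other settings, among them the block, cyclic loess and fry (adjusted p = 0.018, 0.015 and 0.014) and removal of empty vector 1, empty vector 2 or IKZF1 2 (adjusted p = 0.047, 0.041 and 0.014). With an estimated correlation adjusted p was 0.32. Of 16 p53 targets, Sesn2 alone passed, lower, also when adjusted over the list alone, and the list was not shifted (adjusted p = 0.80; median 0.06, mean -0.03).

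Integrin, adhesion and cytoskeleton genes went both ways. Of 34 members, 2 rose, 1 fell and 31 did not pass: the actin crosslinker gene Actn1 (1.52, adjusted p = 0.0099) and the integrin beta chain gene Itgb7 (1.24, adjusted p = 0.029) were higher and Itgal was lower. The counts were 6 higher and 4 lower when adjusted over the list alone, and 6 and 5 with the replicate block. The list had no shift to one side (adjusted p = 0.38). Of 12 Notch targets, Dtx1, a ubiquitin ligase gene of the Notch pathway, rose by 1.21 (adjusted p = 0.0069) and 11 did not pass. Adjusted over the list alone 1 was higher and 1 lower. Hes1 had -0.62 (adjusted p = 0.11, and 0.010 without empty vector 3), and the list was not shifted (adjusted p = 0.34).

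Markers of other cell types that a sorted culture could hold were near background for most lists, at mean log2 levels in the empty vector group from 5.27 for NK and innate lymphoid cells to 9.23 for plasma cells. Of 23 granulocyte and monocyte markers, Ly6g and the adaptor gene Tyrobp (0.62, adjusted p = 0.028) rose, over all genes and adjusted over the list alone, and 21 did not pass. The Fc receptor gene Fcgr3 had 0.76 (adjusted p = 0.13, and 0.0088 with the replicate block, where 3 members were higher), Lyz2 had -0.47 (adjusted p = 0.20) and S100a8, a granulocyte gene chosen after its value was seen, 0.09 (adjusted p = 0.51). As a whole the list was not shifted (adjusted p = 0.30). None of the 13 T cell, 12 NK, 8 erythroid, 12 megakaryocyte and mast cell, 9 plasma cell, 10 dendritic or 17 stromal markers passed in limma, over all genes or adjusted over the list alone, and 1, 1, 2, 0, 2, 0 and 2 of them had an unadjusted p under 0.05. The T cell list was shifted upward (median 0.11, camera adjusted p = 0.049), a call lost with an estimated correlation (adjusted p = 0.64), fry (0.31), brighter genes (0.23), the mean of probe sets (0.051), quantile normalization (0.14), cyclic loess (0.18), the level trend removed (0.16), and without empty vector 1, empty vector 3 or IKZF1 2 (adjusted p = 0.070, 0.41 and 0.15). All 17 stromal markers had a log2 difference above 0 (median 0.07), with a list adjusted p of 0.078 that passed without empty vector 2 (adjusted p = 0.041) or IKZF1 1 (adjusted p = 0.014). With the replicate block 1 of them was higher, the collagen gene Col1a1 (0.30, adjusted p = 0.28 and 0.0499). Adjusted p was 0.34 for the NK list, 0.56 for the erythroid, 0.34 for the megakaryocyte and mast cell, 0.57 for the plasma cell and 0.38 for the dendritic list. In the plasma cell list Prdm1, a regulator of plasma cell differentiation, had 1.17 (adjusted p = 0.12, 0.0043 with the replicate block and 0.035 without empty vector 3). Jchain, the joining chain gene, had 1.87 ± 0.66 (SE; adjusted p = 0.21, and 0.074 with the block), with each IKZF1 array above each empty vector array. Without empty vector 3 it had 1.05 and passed (adjusted p = 0.014). Over all 29 lists, 12 were past the threshold with camera's preset correlation, 6 upward and 6 downward, 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 7 with fry, 6 of them among the 12. Without empty vector 3, 5 lists were past it.

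**Figure D2:**
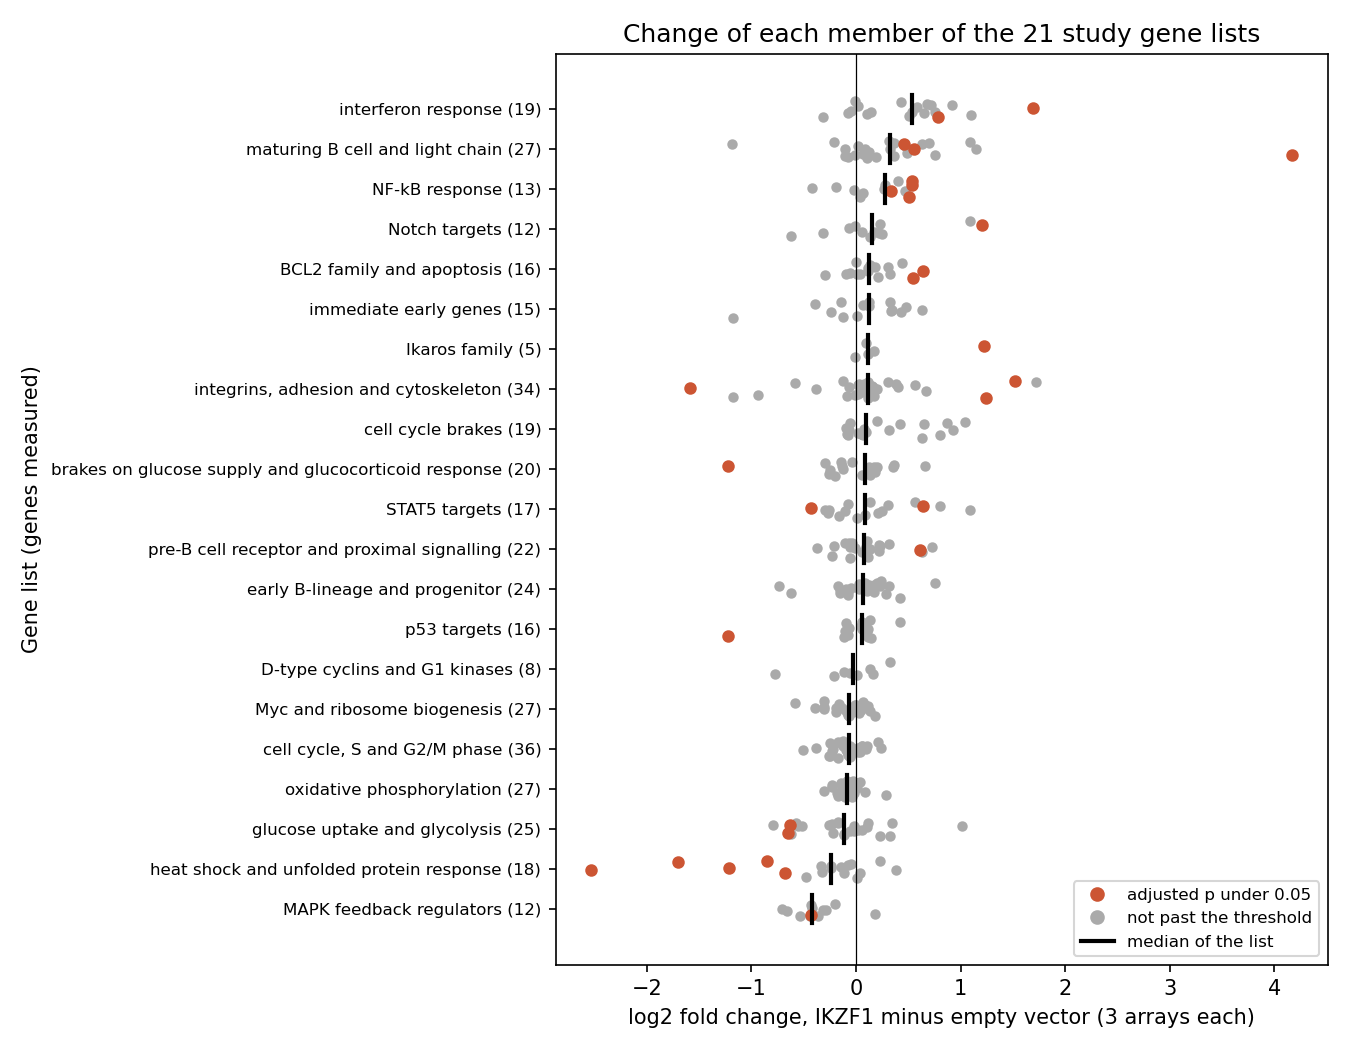
Log2 fold change, IKZF1 minus empty vector (horizontal axis, 3 arrays each), of every measured member of the 21 study gene lists, with the number of genes measured in brackets. Each point is a gene, orange where its adjusted p was under 0.05, and the black bar is the list median, which runs from 0.54 for the interferon response to -0.43 for the MAPK feedback regulators.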

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

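The tests of the level trend and of granulocytes below were chosen only after the results they concern had been seen. In probe sets outside the comparison of named genes, with adjustment over all 35421 probe sets, 120 of the 12011 unnamed ones passed the threshold, 38 higher and 82 lower in the IKZF1 group. What the unnamed ones measure is not known here, so they are not counted as transcripts that changed. By the same adjustment, 142 of the 21789 probe sets with 1 symbol were higher and 139 lower. Of the 1621 probe sets that share several genes, 14 passed, all 14 higher. They are not separate rises: they form 6 groups that share symbols, the largest of 5 probe sets, and 2 probe sets have equal values. Their log2 differences ran from 0.51 to 3.85. Among them, 4 probe sets in 2 of the groups hold a member of the maturing B cell list that the list test left out. All symbols of these probe sets are immunoglobulin light chain genes. Those of Iglv1, Iglc1 and Iglv2 had 3.43 and 3.31, and those of Igkc with Igkv4 segments 0.99 and 0.90 (limma adjusted p from 0.0055 to 0.046). Light chain signal was thus higher, but which of the light chain genes gave it cannot be told. Groups of 3 arrays were not tested for single outlying samples, and with 1 contrast there was no second effect to compare. Empty vector 3 stood furthest apart within its group. Across genes its log2 differences from empty vector 1 and 2 had SDs of 0.34 and 0.45, against 0.19 between empty vector 1 and 2.

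The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 448 genes and the highest of the others 0, so that 1 of the 10 gave as many as the real one. Among the splits that part all 3 same-numbered pairs, fitted with the replicate block, the real one gave 1438 genes and each of the others 0. Every split but the real one mixes the groups, so a difference between them adds to the residual spread. Low counts there could be expected, and the contrast with the real split is no separate support.

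The first pattern is a set of small opposite shifts: lists of bright genes (oxidative phosphorylation, S and G2/M phase, Myc and ribosome biogenesis) moved down and the list of dim T cell markers moved up, without a single member past the threshold in any of the 4. In camera with an estimated correlation all 4 calls were lost (adjusted p = 0.32, 0.73, 0.69 and 0.64). The calls of all other lists were lost there too, so this loss does not set the 4 apart. Across all genes the median log2 difference depended on level, at 0.10 in the fifth of 10 equal groups of genes by level and -0.06 in the eighth. It was -0.03 in both the ninth and the tenth, whose median levels were 10.5 and 11.7. The lists of bright genes had mean levels of 11.7, 11.5 and 11.1 in the empty vector group. After cyclic loess the median lay between -0.03 and 0.03 in each group, at 0.01 in the ninth and 0.02 in the tenth. After cyclic loess 0 of the 4 lists were past the threshold, with adjusted p of 0.20, 0.28, 0.51 and 0.18, and means that had shrunk from -0.08, -0.08, -0.08 and 0.13 to -0.03, -0.03, -0.04 and 0.08. A level-dependent difference between arrays is therefore a candidate explanation for these shifts. A true change of bright transcripts caused by Ikaros stays open, as it would be removed by the same correction.

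The second pattern is the rise of Ly6g by 4.47 on the log2 scale. Granulocytes in the IKZF1 cultures would bring their abundant transcripts, but Camp, Ltf, Ngp, S100a8, S100a9 and Lyz2 had a median log2 difference of 0.029 (SD 0.22), with levels in both groups between 4.95 and 6.75, which argues against them; the sort on GFP would not remove a transduced granulocyte. Among the other measured Ly6 genes the largest difference was 1.33 (SE 0.31, adjusted p = 0.088 in limma, and 0.030 with the replicate block), for Ly6d. It lay between the bound of 2 set for hybridisation of a related Ly6 transcript and that of 1 set against it. Ly6f rose by 0.86 (adjusted p = 0.0069). In the empty vector group Ly6d and Ly6f already stood at log2 levels of 10.53 and 12.16, where the Ly6g probe set read 5.61, within the background range. Rises of that size from such levels would not give 4.47 from background, which argues against Ly6d and Ly6f as the source. Other Ly6 genes with no probe set of 1 symbol were not analysed here, so hybridisation of one of them cannot be told apart from Ly6g itself. A direct or indirect effect of Ikaros on Ly6g in pre-B cells was not tested and stays open.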

How the results depend on the processing

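Alternatives chosen after seeing the data were log2 without a pseudocount, the random block, removal of the level trend, and cyclic loess for lists and named genes. Ikzf1 kept its direction and its side of the threshold in every setting, with log2 differences from 1.18 to 1.28 and adjusted p from 0.00041 to 0.031. With all probe sets tested together, 415 probe sets passed, which is not a count of genes. Of those with 1 symbol, 142 were higher and 139 lower. The count of 448 genes stayed between 402 and 559 with a trended or robust prior, brighter genes, the mean of probe sets, quantile normalization, centring, cyclic loess, no pseudocount or the level trend removed. It was 1481 with array weights, 1438 with the replicate block, 1664 with the random block, 77 at a log2 difference of at least 1 and 57 at an adjusted p under 0.01, the last by construction; without 1 array it ran from 24 (without IKZF1 1, 28 without empty vector 1) to 947 (without empty vector 3), with 163 without empty vector 2 and 83 and 85 without IKZF1 2 and 3. The lower counts go with fewer samples; the cause of the 947 was not tested. The 12 list calls became 0 with an estimated correlation and 7 with fry (6 of the 12), and ran from 5 (without empty vector 3) to 14 without 1 array; the highest adjusted p of each called list lay between 0.21 and 0.75. Among the genes and lists named in the text, the replicate block changed no other call than those given beside them. No named gene past the threshold changed sign. Of 85 named genes that were not past it, 40 passed in some setting: 30 with the random block, 29 with array weights, 24 with the replicate block, 19 without empty vector 3 and at most 6 in any other. The directions that turned were not past the threshold in either setting, except that of S and G2/M phase, whose mean ran from -0.21 to 0.052 (without empty vector 3) with 1 array left out. Likewise Ikzf4 ran from -0.17 to 0.096 and turned without empty vector 2, IKZF1 1 or IKZF1 3, the STAT5 targets ran from -0.036 (without empty vector 3) to 0.26, the p53 targets from -0.092 (without empty vector 3) to 0.029 and the integrins from -0.030 (without empty vector 3) to 0.21; the p53 list also turned without IKZF1 1. The glucose brake list turned upward with fry (mean -0.0056), brighter genes (-0.019), quantile normalization (0.016), centring (-0.048), cyclic loess (0.017), the level trend removed (0.012) and without IKZF1 2, its mean and the test's direction differing in sign in some; without 1 array its mean ran from -0.062 to 0.029. The cause was not tested. Genes within the background range in a group, such as Ly6g and Ms4a1 in empty vector cells, have a fold limited by background signal.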

Other observations

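Of the tests in this part, the separate values of seen and unseen members after cyclic loess were chosen after the median of all members had been seen. The list of ATF4 response genes and its tests were set up after falls of Chac1, Trib3, Asns and similar genes had been seen, but before the values of the members counted below as unseen were read. Further genes of amino acid metabolism, uptake and transfer RNA charging were on that list, and 14 of its 32 unseen members fell while 18 did not pass. The serine hydroxymethyltransferase gene Shmt2 fell by 0.76 and the serine synthesis gene Psat1 by 0.55 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.011 and 0.031). Both chains of the large neutral amino acid transporter, Slc7a5 and Slc3a2, fell by 0.67 (adjusted p = 0.035 and 0.023). Among the aminoacyl-tRNA synthetase genes, log2 differences were -0.97 for Cars, -0.77 for Lars, -0.74 for Sars, -0.64 for Yars and -0.60 for Nars (adjusted p = 0.013, 0.027, 0.0099, 0.012 and 0.019), while Wars had 0.30 (adjusted p = 0.14, and 0.045 with the replicate block) and the transporter genes Slc38a2, Slc7a11 and Slc1a5 had 0.11, 0.01 and -0.03 (adjusted p = 0.45, 0.92 and 0.91). Slc7a11 had a log2 level of 4.76 in the empty vector group, within the background range, so a fall of it could not be seen. Many genes of the list are known to be induced by the transcription factor ATF4 when amino acids run short, and Atf4 itself fell by 0.68 (adjusted p = 0.0073).

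The third pattern is thus a fall of genes of the amino acid response, and the hypothesis is that ATF4 response genes as a set are lower when Ikaros is supplied. Of 17 list members whose values had been seen, 14 fell, all 17 lay below 0 and the median was -1.22, which is no independent evidence. Of 32 members not seen before, 14 fell, 0 rose (18 fell with the replicate block) and 26 lay below 0. The list was chosen because its seen members fell on these same arrays. Unseen members that vary with the seen ones would fall with them, so their values are not independent of that choice. Their median was -0.43 (SD 0.31), and 0 of 10000 random lists matched on level had a median as low, the lowest being -0.13. The random lists were drawn gene by gene, so this comparison does not allow for genes of a list varying together. Over these unseen members alone camera gave p = 1.2e-17, p = 0.037 with an estimated correlation, and fry p = 0.0019. After cyclic loess the median of all members was -0.55, within the SD of 0.67 over seen and unseen members together, so that this value decides little by itself. The unseen members alone kept a median of -0.43 (SD 0.29) after cyclic loess, with 15 lower, 0 higher and 27 below 0, and the seen members one of -1.20 (SD 0.71). This argues against a level-dependent difference between arrays as the whole cause of the fall. The fall may therefore reflect lower ATF4 activity in IKZF1 cells, but a difference in medium, density or time since feeding between the cultures was not tested and could move the same genes.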
